A study of Mus musculus with 35 samples.

How the data were processed

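Total RNA from the left lateral liver of 35 BALB/c mice was amplified, labelled with biotin and measured on 1 array per mouse, 6 h after an intravenous injection of deionized water or of silica particles. The labels place 5 mice in each of 7 groups and say that the mice were randomly assigned. The labels name the arrays' values as biological replicates, so each array was taken as 1 mouse. The replicate numbers were checked as a pairing of mice across groups. Deviations from the group mean correlated across genes at a mean of -0.000692 for arrays with the same number (105 pairs, from -0.104 to 0.111) and at 0.000169 for arrays with other numbers. The numbers were therefore not used as a block, except as an alternative.

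The values are the intensity per probe set as deposited by the authors, on a linear scale. The submitters' processing notes name MAS5, with no version. The scaling of the arrays is not given in the sources used here. The mean of each array after 2% of the values was trimmed at each end ran from 887 to 1139, so the arrays were not all set to 1 value of that mean. No further scaling was applied for the reported values. There are 45101 probe sets in it, of which 64 are control probe sets of the manufacturer. The platform's annotation gives 34945 probe sets 1 gene, 932 several genes and 9160 no gene named here. Of the probe sets with 1 gene, 34741 have a gene identifier that is also in the RefSeq mouse gene table, and 204 do not. That table was used for names only, and it changed 0 symbols. No gene coordinates were used.

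A pseudocount of 12.5, the 10th percentile of all values, was added before the log2 was taken. A probe set was kept when its value exceeded 165, the median of all values, on at least 5 arrays, which left 26864 probe sets. Of these, 22660 have 1 gene. For a gene with several kept probe sets, the one with the highest mean log2 value over the 35 arrays was used, which gave 12678 genes. The table holds no detection or saturation calls, so the filter also served as a floor for folds, and 48037, below which 99.5% of all values lie, as a level above which folds are given as at least. Both uses were chosen after the data had been seen. Probe sets with no gene or with several genes were left out of the gene tests and are described in the closing section.

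Each gene was fitted with limma 3.58.1 in R 4.3.3, with a mean per group over all 35 arrays and no other term, followed by contrasts and empirical Bayes moderation with a trend of the variance on the mean signal. Every adjusted p of a gene is from limma's two-sided moderated test, adjusted by the Benjamini-Hochberg method over the genes of that comparison, with a threshold of 0.05. The standard errors (SE) are the moderated ones of that fit. The comparisons were each of the 6 treated groups against control, the linear slope over the dose of SP70 in mg/kg (control as 0), and 8 direct comparisons between treated groups. The named genes follow a rule: against control, the 10 highest and the 10 lowest log2 fold changes among genes past the threshold whose 5 treated mice all lay on the same side of the control mean, and up to 4 members of each gene list with the smallest adjusted p. Between treated groups and for the slope, the rule takes the 5 highest and the 5 lowest. Members of a list may also be named where the list is described.

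Gene lists for liver, immune and other cell types, 42 in all, with 1042 entries and 993 distinct genes, were written before the data were examined, as were the named-gene rule, the tests and all but 1 of the alternatives. Of the distinct genes, 869 were tested, from 6 to 34 per list. Each list was tested with limma's camera and a correlation between genes estimated from the data, and its p was adjusted over the 42 lists and the 6 comparisons with control together. The lists of the 8 direct comparisons were adjusted together in the same way. Camera with a preset correlation and fry were run as alternatives. Camera compares the genes of a list with the other genes, whereas fry tests whether the genes of a set move, on balance, one way, and does not compare them with other genes. Each list also has a count of members past the threshold adjusted over the list alone.

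The alternatives tried were other pseudocounts, other filters, quantile normalization, centring of each array on its median (chosen after the data had been seen), the mean of all probe sets of a gene, a fit of only the groups compared, the replicate number as a block, and leaving out each mouse in turn. The fit was tested on simulated data with the control means and the spreads of these arrays, in which 200 of 12678 genes were changed in 1 group at a time. The genes varied independently there. In the arrays genes are not independent and in most comparisons far more of them changed, so the false calls do not measure the error in these data. At a log2 change of 1, it recovered 76.1% of the genes changed in the simulated SP70 40 mg/kg group, 73.1% for SP30 10 mg/kg and 80.6% for SP300 10 mg/kg, with 5, 6 and 8 false calls. The sign agreement of SP300 at 10 mg/kg with the other groups was set against 50 simulated draws with no group changed and 50 with only SP300 at 10 mg/kg unchanged, all with shared control mice, and was repeated with split control mice, both chosen after the result had been seen. In these draws the genes varied independently of each other. Each draw took its 148 genes with the smallest p, whether or not they passed the threshold. The number of arrays limits the precision. Tables were read with the R package data.table, version 1.17.8, and figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.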

Results

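The data are array signals of RNA from mouse liver, taken 6 h after intravenous injection of silica particles that are called SP30, SP70 and SP300 and differ in size. There are 7 groups of 5 mice: control mice given deionized water, SP70 at 10, 20 and 40 mg/kg, SP30 at 10 mg/kg, and SP300 at 10 and 200 mg/kg. One experiment asked how the response to SP70 depends on the dose. The other asked how the response depends on particle size, at an equal dose of 10 mg/kg and at doses the study had found toxic, which were the dose of SP30, 40 mg/kg of SP70 and the higher dose of SP300. The median signal of an array ran from 149 to 180, and no pair of arrays was identical. Within groups, arrays correlated at 0.962 to 0.976 across probe sets, which are not independent replicates. The first principal component held 33.0% of the variance. Its scores were -46.6 ± 3.18 (SD, n = 5) in control mice and -47.6 ± 2.82 after SP300 at 10 mg/kg, and reached 31.8 ± 5.72 after SP70 at 40 mg/kg and 40.0 ± 4.48 after SP30. Changes are log2 fold changes against control with the SE of the limma fit and n = 5 mice per group, unless a fold is named. The table gives no detection or saturation calls. A fold is given as at least where a mouse of the lower group had a signal below the filter of 165, or a mouse of the higher group one above 48037, in the brightest 0.5% of all values. Such folds are computed without the pseudocount, from signals raised to 165 where they lie below it. The log2 value of a gene with such signals, with or without a fold beside it, includes the pseudocount of 12.5, depends on it where signals are low, and is no bound. A fold given as at least is itself an estimate and leaves out the spread between mice. The highest signal of an array ran from 98717 to 136014, so 48037 is not a ceiling. A fold marked only for a signal above 48037 may therefore be no lower bound. A called list is one with an adjusted p under 0.05 in camera with an estimated correlation.

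The dose response began with a rise of inflammatory genes at the lowest dose of SP70. After 10 mg/kg, Ccl2, a chemokine that draws monocytes, rose at least 18.9-fold (6.24 ± 0.34), and Cxcl1, which draws neutrophils, rose 36.3-fold (5.18 ± 0.25). The acute phase protein Saa3 rose at least 53.6-fold (5.73 ± 0.12) and Lcn2, which binds bacterial siderophores, at least 34.7-fold (5.11 ± 0.22). Tlr2, a receptor for bacterial lipoproteins, rose at least 38.2-fold (5.28 ± 0.20). Cd163, the haemoglobin scavenger receptor of macrophages, fell at least 7.08-fold (-2.81 ± 0.40). Vsig4, a complement receptor of Kupffer cells, the resident macrophages of the liver, fell 4.25-fold (-2.09 ± 0.47).

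At this dose 12 lists rose and 0 fell as called lists. All 23 NF-kB response genes tested rose, with a median of 2.48 (adjusted p = 0.00113 with an estimated correlation, and 23 past the threshold adjusted over the list alone). Among them were Icam1 (3.68 ± 0.20), an adhesion molecule for leukocytes, and Nfkbie (2.73 ± 0.15), an inhibitor of NF-kB. Of 19 chemokines, 13 rose, 1 fell and 5 did not pass (adjusted p = 0.00113; 16 past the threshold adjusted over the list alone). Of 26 acute phase proteins, 21 rose, with a median of 0.91 (adjusted p = 0.00331, 22 adjusted over the list alone). They included Saa2 (4.55 ± 0.25, at least 23.6-fold) and Steap4 (2.74 ± 0.12, at least 6.67-fold), a metal reductase. Interferon response genes rose in 21 of 27 cases, with a median of 1.08 (adjusted p = 0.00679, 22 adjusted over the list alone). They were led by the GTPases Gbp2 (4.39 ± 0.22, at least 22.1-fold) and Gbp6 (3.27 ± 0.20) and by Ifit1 (2.47 ± 0.21), a sensor of viral RNA. Neutrophil markers rose in 12 of 18 (adjusted p = 0.00516, 14 adjusted over the list alone). S100a8 was at 4.04 ± 0.23 and S100a9, its partner in calprotectin, at 4.01 ± 0.25. Monocyte markers rose in 10 of 12 and fell in 1 (adjusted p = 0.00226, 11 adjusted over the list alone). F13a1, a coagulation factor subunit, was at 3.51 ± 0.16 (at least 8.77-fold) and Vcan, a proteoglycan, at 2.95 ± 0.28 (at least 2.24-fold). Of 30 genes of the unfolded protein response and ATF4 targets, 17 rose (adjusted p = 0.0191, 23 adjusted over the list alone), with the chaperone gene Dnajb9 at 1.59 ± 0.10. Cytokines and their receptors (12 of 20 rose, adjusted p = 0.00226, 13 adjusted over the list alone), immediate early genes (20 of 32 rose and 1 fell, adjusted p = 0.0232, 22 adjusted over the list alone) and genes of apoptosis and cell death (11 of 23 rose, adjusted p = 0.00464, 12 adjusted over the list alone) were called as well. So were JAK-STAT3 response genes (9 of 15 rose and 2 fell, adjusted p = 0.0323, 12 adjusted over the list alone) and genes of the extracellular matrix and adhesion (14 of 27 rose and 1 fell, adjusted p = 0.0222, 17 adjusted over the list alone).

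Markers of Kupffer cells and macrophages did not move one way after SP70 at 10 mg/kg. Of 22 markers, 11 fell and 3 rose, and the list was not called (adjusted p = 0.321 with an estimated correlation; 15 past the threshold adjusted over the list alone). Csf1r, the receptor of the growth factor CSF1, fell (-1.09 ± 0.13), while Lyz2, a lysozyme of macrophages and neutrophils, rose (1.93 ± 0.17), as did Mpeg1 (1.06 ± 0.16), a pore-forming protein of macrophages. Of 24 endothelial markers, 3 fell and 1 rose (adjusted p = 0.681, 4 adjusted over the list alone). In total 2299 of 12678 genes changed, 1578 up and 721 down, and 454 rose and 106 fell by at least 2-fold. The split depended on the scaling: quantile normalization gave 1314 up and 1407 down, and arrays centred on their medians gave 1237 up and 1414 down.

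After SP70 at 20 mg/kg, the markers of Kupffer cells were among the genes that fell most. Cd163 fell at least 8.56-fold (-4.67 ± 0.40), and Clec4f, a lectin made by Kupffer cells, at least 18.0-fold (-4.59 ± 0.47). C1qc, a chain of the complement protein C1q, fell at least 13.4-fold (-4.20 ± 0.35). Saa3 rose at least 78.5-fold (6.28 ± 0.12), Ccl2 at least 18.3-fold (6.20 ± 0.34) and Cd14, the co-receptor for endotoxin, 40.6-fold (5.34 ± 0.26). Creld2, a gene induced by stress of the endoplasmic reticulum, rose (2.69 ± 0.27), as did Manf (1.70 ± 0.19, at least 3.26-fold), a secreted protein of the same response.

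At 20 mg/kg 7 lists rose and 0 fell as called lists. NF-kB response genes rose in 22 of 23 (adjusted p = 0.00703 with an estimated correlation, 22 adjusted over the list alone). Chemokines rose in 14 of 19, with 2 lower (adjusted p = 0.00842, 16 adjusted over the list alone). Acute phase proteins rose in 21 of 26 (adjusted p = 0.0107, 21 adjusted over the list alone). Neutrophil markers rose in 13 of 18 (adjusted p = 0.0151, 14 adjusted over the list alone), with S100a8 at 4.24 ± 0.23. Monocyte markers rose in 10 of 12 and fell in 1 (adjusted p = 0.00738, 11 adjusted over the list alone). Cytokines and their receptors rose in 13 of 20 and fell in 1 (adjusted p = 0.00679, 14 adjusted over the list alone). Genes of the unfolded protein response and ATF4 targets rose in 25 of 30 and fell in 1, with a median of 0.87 (adjusted p = 0.00703, 27 adjusted over the list alone). Kupffer cell and macrophage markers fell in 15 of 22 and rose in 2, with a median of -1.46, but the list was not called (adjusted p = 0.0603 with an estimated correlation, 18 adjusted over the list alone). In total 5020 genes changed, 2376 up and 2644 down, and 625 rose and 418 fell by at least 2-fold. The split depended on the processing. With arrays centred on their medians it was 1993 up and 3526 down, and with the mean of all probe sets of a gene 2493 up and 2307 down.

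After SP70 at 40 mg/kg, Cxcl2, a chemokine for neutrophils, rose at least 152-fold (7.92 ± 0.36), Ier3, an early response gene, at least 78.0-fold (7.22 ± 0.39) and Ccl2 at least 35.8-fold (7.16 ± 0.34). C1qc fell at least 14.1-fold (-6.51 ± 0.35), Clec4f at least 22.8-fold (-6.03 ± 0.47) and Vsig4 at least 32.5-fold (-5.98 ± 0.47). The mean signal of Clec4f was 3784 ± 421 (SD, n = 5) in control mice and 62.0 ± 58.7 at this dose, below the filter of 165, so the size of its fall rests on low signals. Adm, a peptide induced by low oxygen, rose at least 13.2-fold (4.10 ± 0.41), as did Ndrg1 (2.69 ± 0.27), another gene of that response. Kdr, the main receptor of VEGF on endothelial cells, fell (-2.46 ± 0.21), and Ptprb, an endothelial phosphatase, fell as well (-2.23 ± 0.15).

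At 40 mg/kg 11 lists rose and 1 fell as called lists. Markers of Kupffer cells and macrophages fell in 18 of 22 and rose in 1, with a median of -2.23 (adjusted p = 0.0232 with an estimated correlation, 21 adjusted over the list alone). Among them were Csf1r (-2.99 ± 0.13) and Cd5l (-4.43 ± 0.29, at least 15.9-fold lower), a secreted protein of macrophages. The riser was Mpeg1 (0.69). Hypoxia and glycolysis genes rose in 19 of 24 and fell in 1, with a median of 0.99 (adjusted p = 0.0139, 20 adjusted over the list alone), with the glycolytic enzyme gene Aldoa at 1.64 ± 0.12. NF-kB response genes rose in 22 of 23 (adjusted p = 0.00331, 22 adjusted over the list alone). Neutrophil markers rose in 15 of 18, with a median of 2.65 (adjusted p = 0.00464, 16 adjusted over the list alone). Immediate early genes rose in 24 of 32 and fell in 1, with a median of 1.84 (adjusted p = 0.00675, 25 adjusted over the list alone). Examples are Btg2 (3.44 ± 0.20), which slows growth, and Junb (3.43 ± 0.22), a subunit of AP-1. JAK-STAT3 response genes rose in 11 of 15 (adjusted p = 0.00679, 11 adjusted over the list alone), including Socs3 (3.83 ± 0.31), a feedback inhibitor of cytokine signals. Chemokines rose in 15 of 19 and fell in 2 (adjusted p = 0.0055, 18 adjusted over the list alone). Cytokines and their receptors rose in 17 of 20 and fell in 2 (adjusted p = 0.00231, 20 adjusted over the list alone). Acute phase proteins (20 of 26 rose, adjusted p = 0.0134, 20 adjusted over the list alone) and monocyte markers (10 of 12 rose and 1 fell, adjusted p = 0.00675, 11 adjusted over the list alone) were called too. Genes of the unfolded protein response and ATF4 targets (24 of 30 rose, adjusted p = 0.00703, 25 adjusted over the list alone) and of apoptosis (11 of 23 rose and 3 fell, adjusted p = 0.0205, 14 adjusted over the list alone) completed the called lists. Endothelial markers fell in 15 of 24 and rose in 2, with a median of -1.19, without a call of the list (adjusted p = 0.332 with an estimated correlation, 19 adjusted over the list alone). In total 5614 genes changed, 1968 up and 3646 down, and 627 rose and 685 fell by at least 2-fold. Under quantile normalization 2481 rose and 3240 fell.

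**Figure D1:**
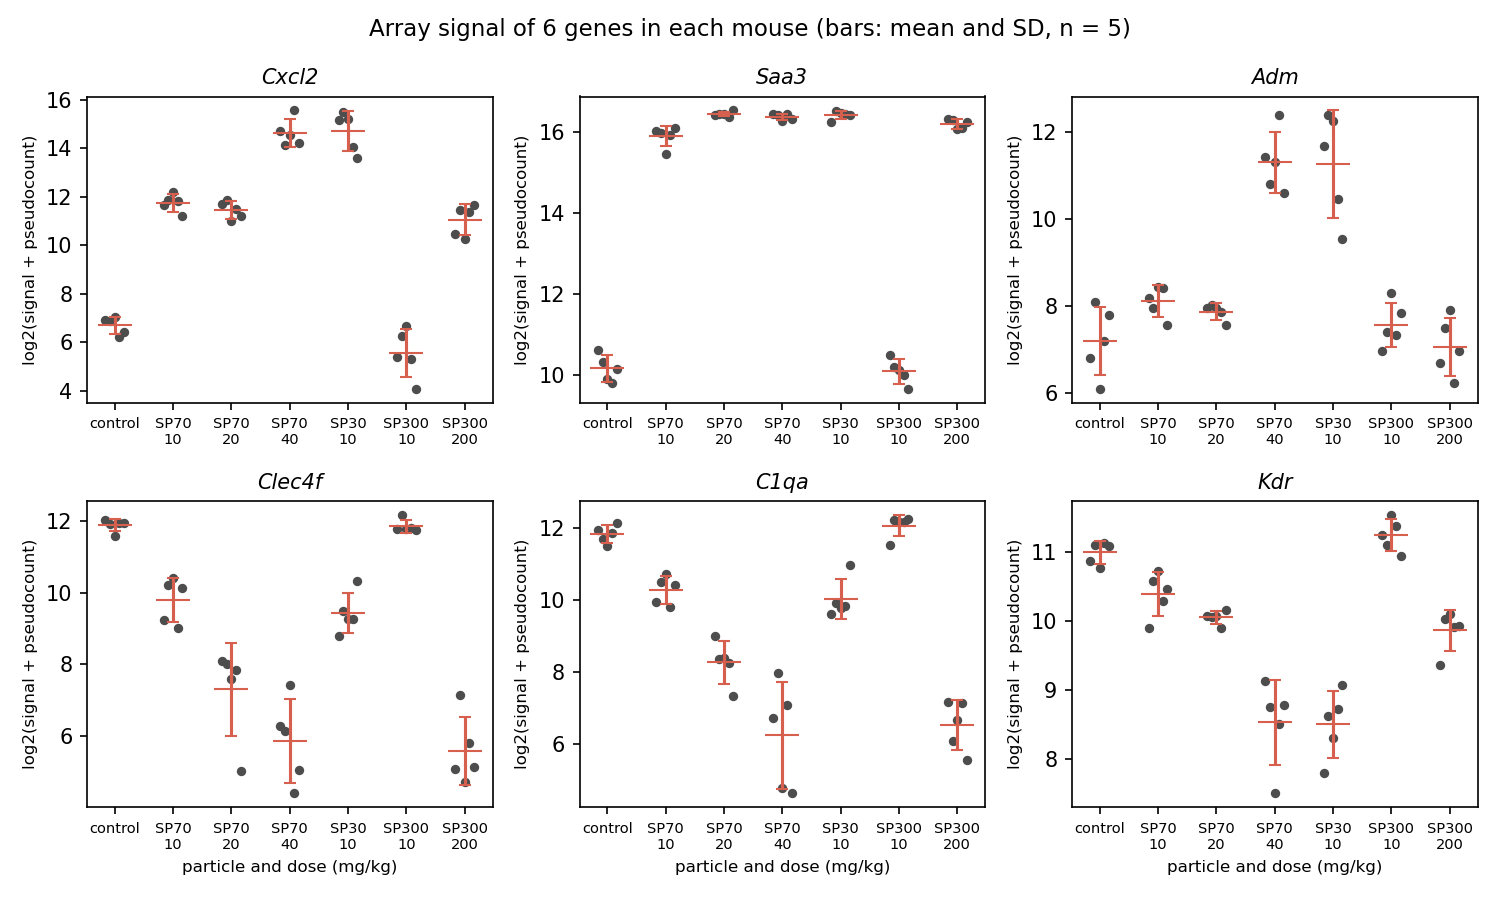
Log2 of the array signal plus pseudocount (vertical axes) in each mouse of the 7 groups (horizontal axes, particle and dose in mg/kg) for Cxcl2, Saa3, Adm, Clec4f, C1qa and Kdr, with bars for the mean and SD (n = 5). Clec4f fell by 6.03 after SP70 at 40 mg/kg and by 2.46 after SP30, while Kdr fell by 2.46 and 2.49.

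Over the doses 0, 10, 20 and 40 mg/kg of SP70, Cxcl2 had the steepest upward slope of log2 signal, 0.17 ± 0.0087 per mg/kg, and Ier3 and Ccl2 followed at 0.17 ± 0.0092 and 0.15 ± 0.0082. C1qc (-0.17 ± 0.0084), Clec4f (-0.15 ± 0.011) and Vsig4 (-0.15 ± 0.011) had the steepest downward slopes. A slope was called for 5709 genes, 1866 upward and 3843 downward, and under quantile normalization 2518 were upward and 3221 downward. The slope is linear in dose, other shapes were not tested, and slopes of genes with low signals depend on the pseudocount. Control counts as dose 0, so a step from control to any dose also gives a slope. Ccl2 was at 6.24, 6.20 and 7.16 against control after 10, 20 and 40 mg/kg, whereas Cd163 was at -2.81, -4.67 and -5.86. The count of slopes is therefore no count of genes that change steadily between the doses.

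The direct comparison of SP70 at 40 with 10 mg/kg gave 3865 genes, and the median log2 difference of all genes was -0.13, and -0.02 with each array centred on its median, as the medians of lists are given here. Ankrd37, a target of the hypoxia factor HIF1, was at least 8.05-fold higher at 40 mg/kg (4.62 ± 0.53) and Adm 9.08-fold (3.18 ± 0.41), and Ier3 was higher as well (3.59 ± 0.39). C1qc was at least 5.25-fold lower (-5.10 ± 0.35), C1qa, another chain of C1q, at least 6.86-fold (-4.03 ± 0.41) and Clec4f at least 5.31-fold (-3.94 ± 0.47). Hypoxia and glycolysis genes were higher in 16 of 24 and lower in 1 (centred median 0.83, adjusted p = 0.00343 with an estimated correlation, 17 adjusted over the list alone). Kupffer cell and macrophage markers were lower in 20 of 22 (centred median -1.61, adjusted p = 0.00808, 22 adjusted over the list alone). Immediate early genes (14 of 32 higher and 1 lower, centred median 0.80, adjusted p = 0.0113, 16 adjusted over the list alone) and JAK-STAT3 response genes (6 of 15 higher, centred median 0.46, adjusted p = 0.0135, 7 adjusted over the list alone) were the other called lists. Interferon response genes were higher in 4 of 27 and lower in 16, with no call (adjusted p = 0.588, 23 adjusted over the list alone). Of the genes called, 660 were higher and 3205 lower; quantile normalization gave 1427 and 1706, and centred arrays 1122 and 2041.

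The equal dose of 10 mg/kg asked for the effect of particle size, and SP30 at this dose changed 6243 genes. Cxcl2 rose at least 161-fold (8.01 ± 0.36), Ccl2 at least 45.5-fold (7.51 ± 0.34) and Ier3 at least 54.2-fold (6.70 ± 0.39). Acod1, which makes itaconate in activated macrophages, rose at least 11.5-fold (6.14 ± 0.23), and Hcar2, a receptor for hydroxybutyrate, at least 17.5-fold (6.46 ± 0.33). Ntn4, a netrin of basement membranes, fell at least 3.69-fold (-4.09 ± 0.25) and Pth1r, the receptor for parathyroid hormone, at least 3.84-fold (-4.06 ± 0.40). Kdr fell (-2.49 ± 0.21), as did Bmp2 (-2.38 ± 0.21), a signal of liver endothelium in the control of iron.

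After SP30 12 lists rose and 0 fell as called lists, while the median of all genes was -0.12. List medians are given with arrays centred on their medians, which left the median of all genes at -0.08. NF-kB response genes rose in 23 of 23 (centred median 2.86, adjusted p = 0.00307 with an estimated correlation, 23 adjusted over the list alone), with Tlr2 at 5.61 ± 0.20 (at least 48.2-fold) and Icam1 at 4.56 ± 0.20. Neutrophil markers rose in 15 of 18 (centred median 3.01, adjusted p = 0.00478, 17 adjusted over the list alone), with S100a8 at 5.43 ± 0.23. Monocyte markers rose in 11 of 12, with 1 lower (centred median 1.86, adjusted p = 0.00584, 12 adjusted over the list alone). Immediate early genes rose in 26 of 32 (centred median 2.13, adjusted p = 0.00679, 28 adjusted over the list alone). Those of hypoxia and glycolysis rose in 17 of 24, with 2 lower (centred median 1.09, adjusted p = 0.0314, 19 adjusted over the list alone), among them Adm (4.06 ± 0.41, at least 12.8-fold) and Aldoa (1.49 ± 0.12). Interferon response genes rose in 20 of 27 (centred median 0.98, adjusted p = 0.0297, 20 adjusted over the list alone). The inflammasome substrate Gsdmd (1.41 ± 0.11) and Bid (2.87 ± 0.12), a link between death receptors and mitochondria, rose among the genes of apoptosis, of which 12 of 23 rose and 2 fell (adjusted p = 0.00679, 14 adjusted over the list alone). Chemokines (15 of 19 rose and 2 fell, adjusted p = 0.00331, 18 adjusted over the list alone), cytokines and their receptors (14 of 20 rose and 1 fell, adjusted p = 0.003, 15 adjusted over the list alone) and acute phase proteins (21 of 26 rose, adjusted p = 0.0103, 21 adjusted over the list alone) were also called. So were JAK-STAT3 response genes (10 of 15 rose, adjusted p = 0.0103, 10 adjusted over the list alone) and genes of the unfolded protein response and ATF4 targets (22 of 30 rose and 1 fell, adjusted p = 0.00905, 24 adjusted over the list alone).

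Endothelial markers fell in 18 of 24 and rose in 1 after SP30, with a centred median of -1.40, but the list was not called (adjusted p = 0.318 with an estimated correlation, 22 adjusted over the list alone). Ptprb (-2.59 ± 0.15) and Ehd3 (-2.10 ± 0.14), an endothelial protein of membrane traffic, were among them, and Lyve1, a hyaluronan receptor of sinusoidal endothelium, was the riser (1.56). Markers of Kupffer cells and macrophages fell in 13 of 22 and rose in 4 (centred median -0.93, adjusted p = 0.668, 17 adjusted over the list alone). The mannose receptor Mrc1 was at -2.25 ± 0.24, the iron exporter Slc40a1 at -1.90 ± 0.18 and Mpeg1 at 1.52 ± 0.16. Genes of bile acid synthesis and transport fell in 18 of 24 and rose in 2 (centred median -0.58, adjusted p = 0.153, 20 adjusted over the list alone), such as Klb (-1.85 ± 0.17), the co-receptor for FGF15. Cholesterol synthesis genes fell in 14 of 20 (centred median -0.88, adjusted p = 0.645, 16 adjusted over the list alone), with Fdft1, squalene synthase, at -1.68 ± 0.23. In total 2285 genes rose and 3958 fell, 768 and 918 of them by at least 2-fold. Under quantile normalization 2682 rose and 3691 fell.

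SP300 at 10 mg/kg changed 148 genes, 117 up and 31 down. Arrdc3, an arrestin-like protein, rose 4.19-fold (2.07 ± 0.44), the transcriptional repressor Bcl6 3.45-fold (1.78 ± 0.31), the methyltransferase Setdb2 2.93-fold (1.55 ± 0.25) and Lpin1, an enzyme of fat synthesis, 2.92-fold (1.54 ± 0.33). Cish, an inhibitor of growth hormone and cytokine signals through STAT5, fell 5.39-fold (-2.43 ± 0.26) and Slc25a30, a mitochondrial carrier, 3.89-fold (-1.96 ± 0.36). Gadd45g, a stress response gene, fell 3.36-fold (-1.75 ± 0.36) and Hhex, a homeobox gene of liver and endothelium, 2.30-fold (-1.20 ± 0.18). Fkbp5, a target of the glucocorticoid receptor, rose (1.21 ± 0.17), as did Foxo1 (0.70 ± 0.13), a factor that insulin holds in check. Saa3 was at -0.07 ± 0.12 and Clec4f at -0.03 ± 0.47, neither of which passed.

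No list was called after SP300 at 10 mg/kg with camera and an estimated correlation, whereas camera with a preset correlation called 10 up and 4 down and fry called 7. The glucocorticoid response genes had the most members past the threshold, 6 of 20 higher and 1 lower, with a median of 0.48 (adjusted p = 0.321 with an estimated correlation, 10 adjusted over the list alone). Acute phase proteins were higher in 4 of 26 (adjusted p = 0.318, 5 adjusted over the list alone), namely Lcn2 (1.47 ± 0.22), the metallothioneins Mt2 (1.70 ± 0.28, at least 3.26-fold) and Mt1 (1.14 ± 0.23, at least 2.21-fold), and Lbp (0.50 ± 0.11), which binds endotoxin. These 4 were not past the threshold when only the arrays of SP300 at 10 mg/kg and control were fitted. Of the 148 genes, 51 were called in the same direction in each of the other 5 treated groups and 36 in none of them. The same sign in all 5 was found for 89, but these comparisons share the control mice. Simulation gave 98 to 128 where no group was changed, and 53 to 82 where only SP300 at 10 mg/kg was unchanged and the others kept their observed means (50 draws each). The latter simulation gave 9 to 39 genes called in all 5. With 2 control mice for SP300 and the other 3 for the rest, in 10 splits, 52 to 77 of the top 148 genes (mean 63.5) had the same sign in all 5. That simulation gave 30 to 55 (mean 40.7), so the ranges overlap only from 52 to 55. All simulated genes varied independently of each other, so the simulated ranges can be too narrow. Across genes, log2 fold changes correlated with those of the other groups at 0.167 to 0.321, and at -0.0597 to 0.151 with split control mice. The simulated correlation of 0.50 holds for 2 unchanged groups. Changed genes in the other group lower it, so it sets no expectation here. The covariances were 0.0355 to 0.0528, against 0.0312 in the same simulation.

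The number of genes after SP300 at 10 mg/kg moved with the fit, to 45 when only the 2 groups compared were fitted, to 72 without SP300 10 mg/kg replicate 3 and to 94 without control replicate 2. The split moved as well, to 73 up and 56 down under quantile normalization and to 70 up and 47 down with centred arrays. Of 12678 genes, 1784 had an unadjusted p under 0.05 in limma's test, a threshold that a share of 0.05 would pass by chance alone.

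**Figure D2:**
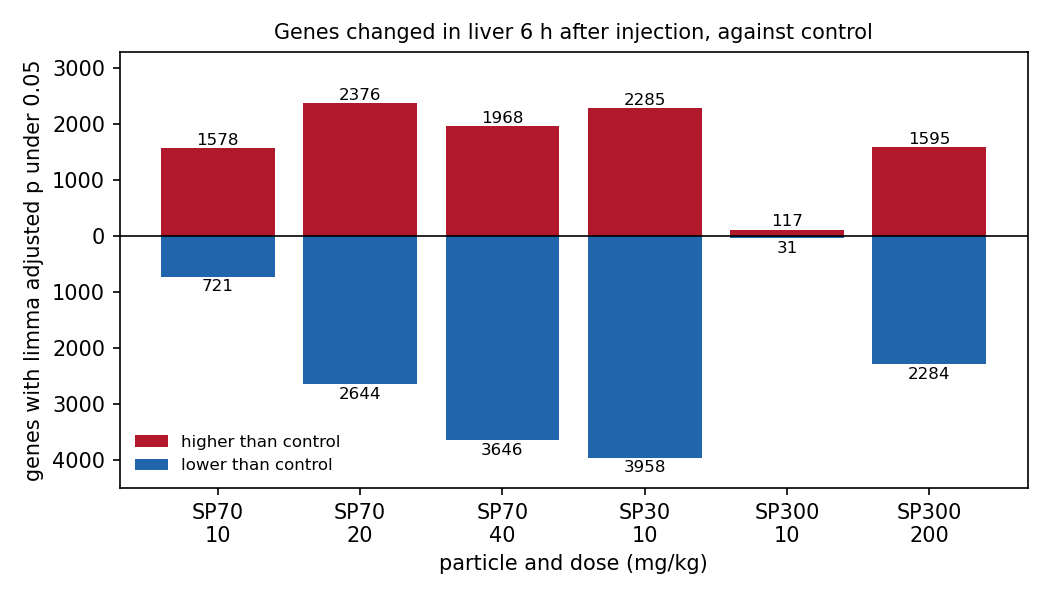
Number of genes with a limma adjusted p under 0.05 (vertical axis, higher than control above 0 and lower than control below it) in each treated group of 5 mice against control (horizontal axis, particle and dose in mg/kg). SP300 at 10 mg/kg had 117 genes up and 31 down, and SP30 at the same dose 2285 up and 3958 down; the split of SP70 at 10 mg/kg, 1578 up and 721 down, turns to 1314 and 1407 under quantile normalization.

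Between the particles at 10 mg/kg, SP30 and SP70 differed in 3665 genes. Ankrd37 was at least 4.33-fold higher after SP30 (3.75 ± 0.53), Adm 8.84-fold (3.14 ± 0.41), Cxcl2 7.76-fold (2.96 ± 0.36) and Nrg4, a growth factor of the epidermal growth factor family, 5.30-fold (2.41 ± 0.22). Ntn4 was at least 2.40-fold lower (-3.48 ± 0.25) and Bmp2 4.86-fold lower (-2.28 ± 0.21). The median difference of all genes was -0.13, and -0.01 with centred arrays, from which the list medians are. Genes of hypoxia and glycolysis were higher after SP30 in 15 of 24 and lower in 1 (centred median 0.79, adjusted p = 0.00343 with an estimated correlation, 18 adjusted over the list alone). Immediate early genes were higher in 18 of 32 (centred median 0.85, adjusted p = 0.00566, 22 adjusted over the list alone) and JAK-STAT3 response genes in 10 of 15 (0.74, adjusted p = 0.0113, 10 adjusted over the list alone). Neutrophil markers were higher in 8 of 18 (centred median 0.97, adjusted p = 0.0116, 9 adjusted over the list alone) and NF-kB response genes in 11 of 23 (0.73, adjusted p = 0.044, 11 adjusted over the list alone). Cytokines and their receptors were higher in 5 of 20, with 1 lower (centred median 0.38, adjusted p = 0.0209, 7 adjusted over the list alone), and genes of the unfolded protein response and ATF4 targets in 8 of 30 (0.28, adjusted p = 0.044, 8 adjusted over the list alone). Endothelial markers were lower in 19 of 24 (centred median -1.05), without a call (adjusted p = 0.159 with an estimated correlation, 19 adjusted over the list alone). Of the genes called, 681 were higher and 2984 lower; quantile normalization gave 1352 and 1810, and centred arrays 1280 and 1705.

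SP30 and SP300 at 10 mg/kg differed in 6559 genes, 2057 higher and 4502 lower after SP30, or 2715 and 3740 under quantile normalization, and the median difference of all genes was -0.18, or -0.09 with centred arrays. Cxcl2 was at least 161-fold higher after SP30 (9.15 ± 0.36), Ccl2 at least 45.5-fold (8.27 ± 0.34) and Il1rn, the antagonist of the IL-1 receptor, at least 69.4-fold (6.91 ± 0.33). Ntn4 was at least 5.20-fold lower (-4.58 ± 0.25) and G0s2, an inhibitor of fat breakdown, 19.7-fold lower (-4.30 ± 0.49). In this comparison 12 lists were called, all higher after SP30, among them NF-kB response genes (22 of 23, centred median 3.00, adjusted p = 0.00249 with an estimated correlation, 22 adjusted over the list alone) and immediate early genes (29 of 32, 2.41, adjusted p = 0.00249, 29 adjusted over the list alone).

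SP70 and SP300 at 10 mg/kg differed in 2609 genes, 1322 higher and 1287 lower after SP70. The split depended on the scaling, with 1327 higher and 1636 lower under quantile normalization and 1268 and 1824 with centred arrays. Ccl2 was at least 18.9-fold higher after SP70 (7.01 ± 0.34), Cxcl2 at least 20.7-fold (6.20 ± 0.36) and Tlr2 at least 45.8-fold (5.65 ± 0.20), while Cd163 was at least 8.02-fold lower (-2.98 ± 0.40). Here 11 lists were called, all higher after SP70, including chemokines (14 of 19 and 1 lower, adjusted p = 0.000568 with an estimated correlation, 15 adjusted over the list alone) and interferon response genes (22 of 27, adjusted p = 0.00361, 22 adjusted over the list alone).

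**Figure D3:**
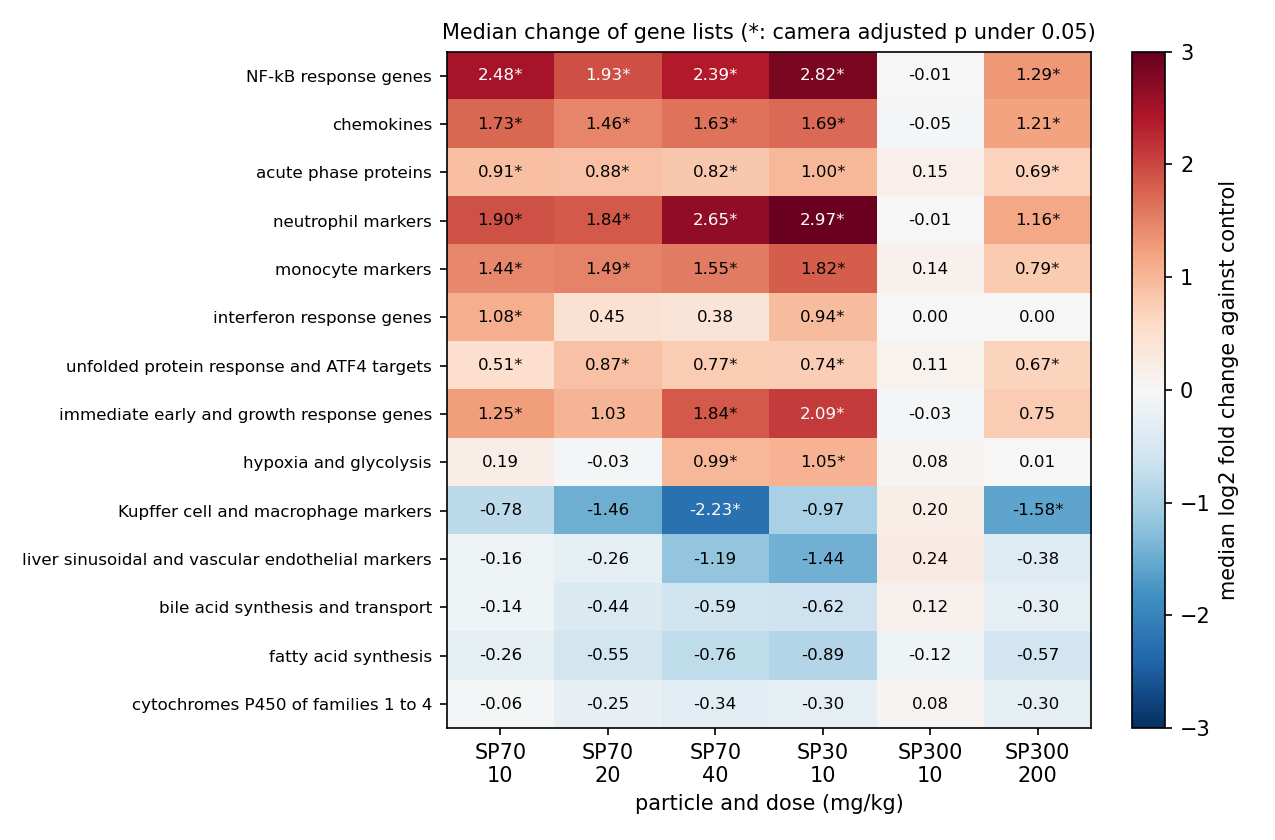
Median log2 fold change against control (colour and printed value) of 14 gene lists in the 6 treated groups of 5 mice (horizontal axis, particle and dose in mg/kg), with a star where camera with an estimated correlation gave an adjusted p under 0.05. The median of Kupffer cell and macrophage markers was -2.23 after SP70 at 40 mg/kg, -1.58 after SP300 at 200 mg/kg and -0.97 after SP30, and that of hypoxia and glycolysis genes 0.99, 0.01 and 1.05; for SP70 at 20 mg/kg the latter was -0.03, while its test pointed up (adjusted p = 0.868).

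SP300 at 200 mg/kg, the last of the toxic doses, changed 3879 genes. Clec4f fell at least 22.8-fold (-6.31 ± 0.47), C1qc at least 14.1-fold (-6.04 ± 0.35) and Vsig4 at least 30.5-fold (-5.46 ± 0.47). Saa3 rose at least 66.3-fold (6.04 ± 0.12), Lcn2 at least 35.7-fold (5.15 ± 0.22), and Cxcl9, a chemokine induced by interferon gamma, 27.4-fold (4.78 ± 0.22). Kupffer cell and macrophage markers fell in 19 of 22 and rose in 1, with a median of -1.58 (adjusted p = 0.00675 with an estimated correlation, 20 adjusted over the list alone), and this list was the 1 called downward. The 7 lists called upward were NF-kB response genes (19 of 23 rose and 1 fell, adjusted p = 0.0107, 21 adjusted over the list alone), chemokines (13 of 19 rose and 3 fell, adjusted p = 0.00703, 16 adjusted over the list alone), cytokines and their receptors (11 of 20 rose and 2 fell, adjusted p = 0.0182, 13 adjusted over the list alone) and 4 more. These were acute phase proteins (20 of 26 rose, adjusted p = 0.0106, 22 adjusted over the list alone), neutrophil markers (10 of 18 rose, adjusted p = 0.013, 12 adjusted over the list alone), monocyte markers (8 of 12 rose and 1 fell, adjusted p = 0.0151, 9 adjusted over the list alone) and genes of the unfolded protein response and ATF4 targets (19 of 30 rose and 1 fell, adjusted p = 0.00722, 22 adjusted over the list alone). Hypoxia and glycolysis genes were higher in 5 of 24 and lower in 6, with a median of 0.01, a mean of -0.11 and a test that pointed down (adjusted p = 1.0, 11 adjusted over the list alone). Interferon response genes were higher in 5 of 27, with a median of 0.00 and a mean of 0.44 (adjusted p = 0.557, 5 adjusted over the list alone). Of the genes changed, 1595 rose and 2284 fell; under quantile normalization 1989 rose and 1984 fell, and with centred arrays 1953 and 1810. The ratio of 3' to 5' signal of the actin control probe sets, a sign of RNA length, was lower than in control mice (2.37 ± 0.11, SD, n = 5) in every treated group, at 1.89 ± 0.13 in this group, 2.08 ± 0.14 after SP300 at 10 mg/kg and 2.11 to 2.20 in the other 4. That of Gapdh did not move one way: it was 0.788 ± 0.025 in control mice, 0.766 ± 0.037 in this group and 0.760 ± 0.034 after SP300 at 10 mg/kg, but 0.810 ± 0.018 after SP70 at 10 mg/kg and 0.829 ± 0.029 after SP30.

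Against SP300 at 10 mg/kg, the dose of 200 mg/kg changed 4015 genes, and the median difference of all genes was -0.11. Saa3 was at least 69.4-fold higher at 200 mg/kg (6.10 ± 0.12) and Ccl2 at least 7.67-fold (5.72 ± 0.34), while Clec4f was at least 22.4-fold lower (-6.29 ± 0.47) and C1qc at least 14.8-fold (-6.11 ± 0.35). Markers of Kupffer cells and macrophages were lower in 19 of 22 and higher in 1 (centred median -1.76, adjusted p = 0.00465 with an estimated correlation, 20 adjusted over the list alone). Chemokines were higher in 12 of 19 and lower in 3 (centred median 1.10, adjusted p = 0.00343, 16 adjusted over the list alone). Of the genes called, 1189 were higher and 2826 lower; quantile normalization gave 1816 and 1859, and centred arrays 1780 and 1847.

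At the toxic doses of the 3 particles (10 mg/kg of SP30, 40 of SP70 and 200 of SP300), 2844 genes changed in the same direction in all 3 groups, 1075 up and 1769 down, or 1417 up and 1527 down under quantile normalization. Dnajb9 rose in each, by 1.70, 1.74 and 1.73 (each ± 0.10). Csf1r fell in each, by 1.40, 2.99 and 3.21 (each ± 0.13). Independent groups of these sizes would share 44.6 genes up and 205 down. The groups share the control mice, however, so that unchanged groups would also correlate, at 0.50 in simulation. Across genes, which are not independent replicates, log2 fold changes correlated at 0.887 between SP70 and SP30, 0.821 between SP70 and SP300 and 0.745 between SP30 and SP300. The covariances were 0.524, 0.345 and 0.341 against 0.0312 in simulation. With 2 control mice for one particle and 3 for the other, in 10 splits, the correlations were 0.761 to 0.806, 0.673 to 0.728 and 0.613 to 0.656.

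Direct tests between the toxic doses found differences as well. SP30 and SP70 differed in 726 genes, 468 higher and 258 lower after SP30. C1qc was at least 4.06-fold higher after SP30 (4.73 ± 0.35), Mmp13, a collagenase, at least 4.75-fold (4.05 ± 0.56) and Cd5l, low in 3 mice after SP70, was higher too (4.02 ± 0.29). Kupffer cell and macrophage markers were higher after SP30 in 16 of 22 (centred median 1.52, adjusted p = 0.000568 with an estimated correlation, 19 adjusted over the list alone). So were 7 of 27 interferon response genes (adjusted p = 0.0445, 13 adjusted over the list alone) and 5 of 23 genes of apoptosis (adjusted p = 0.02, 7 adjusted over the list alone). Of 24 endothelial markers, 0 differed past the threshold (median -0.16, adjusted p = 0.74, 0 adjusted over the list alone). The count was 418 when only these groups were fitted, 429 without SP70 40 mg/kg replicate 3 and 469 without SP30 10 mg/kg replicate 4.

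SP30 at 10 and SP300 at 200 mg/kg differed in 3688 genes, 1474 higher and 2214 lower after SP30. Pfkfb3, which drives glycolysis, was 19.1-fold higher after SP30 (4.25 ± 0.33) and Adm at least 13.8-fold (4.20 ± 0.41), while G0s2 was 16.7-fold lower (-4.06 ± 0.49) and Sox17, a transcription factor of endothelium, at least 2.17-fold lower (-2.48 ± 0.38). Hypoxia and glycolysis genes were higher after SP30 in 19 of 24 (median 0.91, adjusted p = 0.00338 with an estimated correlation, 20 adjusted over the list alone). Markers of Kupffer cells and macrophages were higher in 17 of 22, with 2 lower (median 1.65, adjusted p = 0.00594, 22 adjusted over the list alone), and interferon response genes in 21 of 27 (0.92, adjusted p = 0.0135, 21 adjusted over the list alone). JAK-STAT3 response genes were higher in 14 of 15 (median 1.48, adjusted p = 0.00323, 14 adjusted over the list alone) and NF-kB response genes in 22 of 23 (1.86, adjusted p = 0.00249, 22 adjusted over the list alone). Endothelial markers were lower in 18 of 24 (median -0.83), without a call (adjusted p = 0.21, 18 adjusted over the list alone).

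SP70 at 40 and SP300 at 200 mg/kg differed in 1954 genes, 636 higher and 1318 lower after SP70. Ankrd37 was at least 8.05-fold higher after SP70 (4.62 ± 0.53), Adm at least 14.2-fold (4.24 ± 0.41) and Rnd1, a small GTPase that loosens the actin skeleton, 13.1-fold (3.71 ± 0.40), while Armcx4 was at least 4.08-fold lower (-2.13 ± 0.30). Genes of hypoxia and glycolysis were higher after SP70 in 18 of 24 (median 0.96, adjusted p = 0.000568 with an estimated correlation, 19 adjusted over the list alone) and JAK-STAT3 response genes in 14 of 15 (1.37, adjusted p = 0.000568, 14 adjusted over the list alone). Immediate early genes were higher in 24 of 32 (median 1.26, adjusted p = 0.0006, 28 adjusted over the list alone). Markers of Kupffer cells and macrophages differed in 1 of 22, lower after SP70, with a median of -0.21 and a mean of -0.13 but a test that pointed up (adjusted p = 0.999, 1 adjusted over the list alone).

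Against control, camera with an estimated correlation called 51 of the list comparisons in the 6 groups, with a preset correlation 134, and fry called 164. The 51 were the lists given above as called, and every list comparison given with a p over 0.05 lacks a call with the estimated correlation. Some called lists share genes, so they are not separate results. Of the JAK-STAT3 response genes, Bcl3 and Cebpd are also NF-kB response genes, and Fos, Junb and Myc are immediate early genes. Il4ra is also in the cytokine list and Mcl1 in that of apoptosis.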

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

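The comparison of Kupffer with endothelial markers, the tests of the genes changed by SP300 at 10 mg/kg, and the count of endothelial markers above their median were chosen after the results were seen. The tests of scaling for Kupffer and hypoxia genes and the splits of the mice were chosen before.

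In a list written before the data were seen, Kupffer cell and macrophage markers were lower after SP70 at 40 mg/kg than after SP30 at 10 mg/kg; of its most abundant genes, Csf1r had mean signals of 1320 and 4069 and Vsig4 of 108 and 907, but Slc40a1 of 6551 and 5119. Array scaling is argued against as the whole cause. The median difference, SP30 minus SP70, was 1.54 under quantile normalization and 1.5 as deposited. A 95% bootstrap interval over markers ran from 0.98 to 2.66. Such intervals resample genes, which are not independent, and carry no spread between mice. The median endothelial marker differed by -0.16, and the Kupffer median exceeded it by 1.66 (1.05 to 2.69). The Kupffer difference was thus not shared by endothelial markers. Most endothelial markers fell in both groups against control, though, so they cannot gauge the share of all cells other than hepatocytes. A lower share of cells other than hepatocytes at 40 mg/kg of SP70 stays open. So does a larger loss of Kupffer cells, or less of these RNAs in the same cells. The arrays cannot separate them. Particle size and dose differ together here, so no biological explanation was tested. Of the 22 markers, C1qa and C1qb are also in the complement list.

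The genes changed by SP300 at 10 mg/kg are the second pattern. Array scaling is argued against for most of them, since 104 of the 148 were called in the same direction under quantile normalization. Control mice that stand apart from every treated group could give such genes too: 89 of the 148 had the same sign in all other 5 treated groups, where simulation gave 98 to 128 with no group changed and 53 to 82 with only this group unchanged. With the control mice split, 52 to 77 of the top 148 genes did (mean 63.5), against 30 to 55 (mean 40.7) in simulation with only this group unchanged. These ranges overlap only from 52 to 55. The simulated genes varied independently, so the simulated ranges can be too narrow. A shift of all control mice alike would also pass such a split. Control mice that stand apart therefore cannot be told apart from a response to injected particles. The 3' to 5' ratio of actin was lower in every treated group than in control mice (2.08 ± 0.14, SD, n = 5, in this group against 2.37 ± 0.11), but that of Gapdh was 0.760 ± 0.034 against 0.788 ± 0.025 and above control after SP70 at 10 mg/kg and SP30, so RNA length stays open and untested, as does a biological effect of the particle at this dose.

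After SP30 at 10 mg/kg, hypoxia and glycolysis genes were higher than after SP300 at 200 mg/kg, and endothelial markers, a list also written beforehand that shares only Vwf with another list, were low (mean signal of Clec4g 1431 against 7501 in control, of Fcgr2b 1776 against 5221). Scaling is argued against for the hypoxia list, since its median difference was 0.91 both under quantile normalization and as deposited. The bootstrap interval over genes, 0.52 to 1.19, again carries no spread between mice. The endothelial markers did not all fall alike, since 9 of the 24 had a 95% interval above the list median of -1.44 against control. Low signals and the pseudocount can also make falls unequal, so a loss of endothelial cells cannot be judged from this spread. A loss of endothelial cells, a change of the blood supply, or unequal changes within endothelial cells may still lie behind these values. None of these was tested, and size and dose again differ together.

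In 133 groups of 5 values (19 measures in 7 groups), 14 had a value far from the other mice of its group, where chance gives about 1 in 20. The signal of Saa3 was 45300 in replicate 3 of SP70 at 10 mg/kg (others 63000 to 70000). That of Cxcl2 was 48000 in replicate 4 of SP70 at 40 mg/kg (17800 to 26500). That of Ccl2 was 9420 in replicate 2 of SP30 (6840 to 7520). Lcn2 was at 11700 in replicate 5 of SP300 at 10 mg/kg (3970 to 5580). Clec4f was at 3050 in control replicate 3 (3850 to 4140). It was at 4590 in replicate 2 of SP300 at 10 mg/kg (3420 to 3560) and 127 in replicate 2 of SP300 at 200 mg/kg (13.6 to 43.5). C1qa was at 2000 in replicate 5 of SP30 (769 to 952). It was at 2940 in replicate 1 of SP300 at 10 mg/kg (4510 to 4790). Lyve1 was at 2210 in control replicate 5 (462 to 944). Mt2 was at 70600 in replicate 1 of SP30 (78600 to 80700). Hspa5 was at 54700 in replicate 3 of SP70 at 40 mg/kg (62800 to 66100). The 3' to 5' ratio of the Gapdh control probe sets was 0.721 in replicate 3 of SP70 at 20 mg/kg (0.796 to 0.813). That of actin was 1.66 in replicate 5 of SP300 at 200 mg/kg (1.9 to 1.98).

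Lists differed between the toxic doses in the direct tests, all with limma's camera, an estimated correlation and an adjusted p. SP30 was higher than SP70 in Kupffer cell and macrophage markers (0.000568), genes of apoptosis (0.02) and interferon response genes (0.0445). Against SP300, SP30 was higher in NF-kB response genes (0.00249), immediate early genes (0.00249), JAK-STAT3 response genes (0.00323), hypoxia and glycolysis genes (0.00338), and cytokines and their receptors (0.00357). It was also higher in genes of apoptosis (0.00379), Kupffer cell and macrophage markers (0.00594), neutrophil markers (0.00984), monocyte markers (0.0107), chemokines (0.0108) and interferon response genes (0.0135). SP70 was higher than SP300 in JAK-STAT3 response genes (0.000568), hypoxia and glycolysis genes (0.000568), and immediate early genes (6e-04). It was also higher in cytokines and their receptors (0.00249), NF-kB response genes (0.00249), neutrophil markers (0.0113), monocyte markers (0.0235) and genes of apoptosis (0.0235).

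Probe sets with no gene or several genes, 4204 of them above the filter, were not used in the gene tests. Against control, 413 of them changed after SP70 at 10 mg/kg, 933 at 20 mg/kg and 887 at 40 mg/kg. The numbers were 1029 after SP30, 64 after SP300 at 10 mg/kg and 526 at 200 mg/kg.

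For each count, 100 splits of the same mice into groups of the same sizes were fitted, the real one included. Only the real one of the 100 gave a count as large, in each case. A share of 1 in 100 is the smallest such a test can give. It was run for many counts, so chance is not excluded. Against control, the real and the highest other count were 2299 and 1180 for SP70 at 10 mg/kg, 5020 and 2249 at 20 mg/kg, and 5614 and 2848 at 40 mg/kg. They were 6243 and 3178 for SP30, 148 and 55 for SP300 at 10 mg/kg, and 3879 and 1687 at 200 mg/kg. The slope over the dose of SP70 gave 5709 and 3795, and SP70 at 40 against 10 mg/kg 3865 and 2277. At 10 mg/kg, SP30 against SP70 gave 3665 and 2054, SP30 against SP300 6559 and 3717, and SP70 against SP300 2609 and 1119. Between toxic doses, SP30 against SP70 gave 726 and 472, SP30 against SP300 3688 and 827, and SP70 against SP300 1954 and 346. SP300 at 200 against 10 mg/kg gave 4015 and 1614. The called lists gave 51 and 4, and the genes shared by the 3 toxic doses 2844 and 0. For the lists and the shared genes, all 35 mice were split over all 7 groups, which mixes strongly different groups. Low counts in the other splits are then likely in any case, so nothing about agreement is read from them.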

How the results depend on the processing

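Centring of each array on its median was chosen after the data had been seen; the other settings were chosen before. Of 919 values of a named gene in a comparison, 92 fell short of the threshold under some setting and 1 turned: Hspa4l after SP70 at 20 mg/kg was 0.02 with the mean of all probe sets (the cause was not tested). Short of the threshold fell 35 of 919 with the mean of probe sets, 45 with only the groups compared (fewer samples), 16 with no filter, 15 with centring, 10 with quantile normalization, 3 with the 30th percentile as pseudocount and 0 with a pseudocount of 1. It was 0 of 838 with the filter at the 75th percentile, and 224 of 9290 with a mouse left out. With the replicate number as a block, 5 of 919 did, and no count moved by over 1.5 times. The called lists were 51, but 134 with a preset correlation and 164 with fry. The preset correlation asks the same question of each list, so the number called rests on the correlation taken, while fry asks another question. After SP300 at 10 mg/kg, 45 genes passed with only the 2 groups fitted, against 148, and 72 (without SP300 10 mg/kg replicate 3) to 164 (without its replicate 4) with a mouse left out, with 94 without control replicate 2. Between SP30 at 10 and SP70 at 40 mg/kg, 418 passed with only these groups, against 726, and 429 (without SP70 replicate 3) to 856 (without SP30 replicate 1), with 469 without SP30 replicate 4. The other counts stayed within 1.5 times under each setting run. With a mouse left out they ran from 1895 to 2416 for SP70 at 10 mg/kg, 4647 to 4925 at 20, 5163 to 5464 at 40, and 5853 to 6020 for SP30. They ran from 3225 to 3770 for SP300 at 200 mg/kg, 5187 to 5792 for the slope and 50 to 54 for the lists. The genes shared by the toxic doses ran from 2475 to 2876. In the direct comparisons they ran from 3307 to 3916 for SP70 at 40 against 10 mg/kg and 3501 to 3954 for SP300 at 200 against 10 mg/kg. At 10 mg/kg they ran from 3054 to 3731 for SP30 against SP70, 6123 to 6382 for SP30 against SP300 and 2073 to 2748 for SP70 against SP300. Between toxic doses they ran from 3057 to 3520 for SP30 against SP300 and 1460 to 1984 for SP70 against SP300. Signal over background limits folds in both directions: of 909 comparisons of a named gene between groups, 125 had all 5 mice of the lower group below the filter of 165, and their log2 values depend on the pseudocount. Ccl2 after SP70 at 10 mg/kg, with a mean signal of 40.5 in control mice, was at 6.24, or at 6.88 with a pseudocount of 1, and Clec4f had a mean signal of 45.6 after SP300 at 200 mg/kg. At the other end, 46 had all 5 mice of the higher group above 48037, as Saa3 and Lcn2 after SP300 at 200 mg/kg; whether such signals are saturated is not given in the sources used here, so no dose shape is read from them.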

Other observations

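None of the lists of liver metabolism in this paragraph was called with an estimated correlation, and members are given for SP70 at 40 mg/kg, with 1 gene after SP30. After SP70 at 40 mg/kg, 19 of 34 cytochrome P450 genes fell (adjusted p = 0.319 with an estimated correlation in limma's camera, 19 adjusted over the list alone), such as Cyp4f15 (-1.22 ± 0.12, SE, n = 5 per group). Conjugation enzymes fell in 21 of 27 and rose in 1 (adjusted p = 0.191, 25 adjusted over the list alone), with Tpmt, which methylates thiopurines, at -0.93 ± 0.11. Of 28 genes of gluconeogenesis and amino acid catabolism, 17 fell and 5 rose (adjusted p = 0.668, 22 adjusted over the list alone): G6pc, glucose-6-phosphatase, was at -2.50 ± 0.25, Hal, which breaks down histidine, at -2.08 ± 0.17 and Igfbp1, a binding protein of insulin-like growth factors, at 3.75 ± 0.42 (at least 13.5-fold). Fatty acid synthesis genes fell in 14 of 21 and rose in 1 (adjusted p = 0.553, 17 adjusted over the list alone), with Acly, ATP citrate lyase, at -1.38 ± 0.23 and Dgat2, which makes triglycerides, at 0.77 ± 0.08. Genes of oxidative phosphorylation fell in 28 of 29, by small amounts (median -0.33, adjusted p = 0.36, 28 adjusted over the list alone), as Sdhd, a subunit of succinate dehydrogenase, at -0.57 ± 0.075. The median of all genes after SP70 at 40 mg/kg was -0.094. After SP30, Nr1i3, the receptor CAR that controls drug metabolism, fell (-2.12 ± 0.17).

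The lists in this paragraph, given for SP30 at 10 mg/kg, were not called either. Actin cytoskeleton genes rose in 15 of 25 and fell in 1 (adjusted p = 0.133 with an estimated correlation in limma's camera, 17 adjusted over the list alone), with Tpm4, a tropomyosin, at 1.74 ± 0.14 (SE, n = 5 per group). Hmox1, heme oxygenase, rose (3.74 ± 0.32) while 7 of 25 NRF2 targets rose and 10 fell (adjusted p = 0.875, 19 adjusted over the list alone), a list with a median of -0.21, a mean of 0.08 and a test that pointed up. Stellate cell markers rose in 3 of 20 and fell in 8 (adjusted p = 0.771, 11 adjusted over the list alone), with Timp1, an inhibitor of matrix proteases, at 2.32 ± 0.29 (at least 3.93-fold) and Lrat, which stores retinol, at -2.48 ± 0.26 (at least 5.56-fold lower). Of 27 proteasome genes, 13 rose (adjusted p = 0.406, 13 adjusted over the list alone), led by the immunoproteasome subunit Psmb10 (1.61 ± 0.10).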
